A study of Mus musculus with 11 samples.

How the data were processed

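Gene expression was measured by 3′ mRNA sequencing (QuantSeq, forward kit) of RNA from mouse cerebellar tumours of strain CD1 that were frozen fresh. Per the labels' protocols, total RNA was extracted with TRIzol and unique molecular identifiers were added when the complementary strand was made. Per the submitters' processing notes, the tools named were STAR 2.4.1d and HTSeq 0.6.1, with the mouse build mm10. The annotation release, the strand setting and whether reads sharing an identifier were collapsed are not given in the sources used here. The deposited table held raw counts per gene symbol, 1 column per library, with no normalization by the authors. Each column was matched to its library by its name in the labels. Because the collapse of identifiers is not stated, floors and intervals drawn from the counts cover counting error only.

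The 11 libraries fell into 4 groups by title. Library totals ran from 2.58 to 15.19 M counts. The constitutive MYC/Gfi1 tumours had 7.53 and 6.53 M, and the constitutive MYC/Otx2 tumours had 6.97, 7.24 and 8.33 M. The tumours from S100b-positive cells had 15.19, 14.84 and 12.77 M, and the N1ICD tumours had 2.68, 3.38 and 2.58 M. No label says that the samples of a group came from separate animals, so each p-value rests on a spread between libraries. That spread was pooled over the 4 groups, so it is not only that of the groups compared. Ddx3y of the Y chromosome was present in 1 library and near 0 in the others of the constitutive MYC/Gfi1, the MYC/Otx2 and the N1ICD groups, so each of these held at least 2 animals. The number of animals behind the S100b-cell libraries stays open. Chi-square values per degree of freedom between libraries of a group ran from 22.6 to 139.68, so no pair held copies of the same counts. This does not show that the libraries are independent, and each was used as a replicate because the labels number it as one. The column names in the labels follow 3 styles. The constitutive groups share a style and the S100b-cell and N1ICD groups each have their own. A difference between library sets therefore cannot be told apart from the groups, except between the constitutive groups.

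Of 38406 genes in the table, 15228 passed the low-count filter of edgeR 4.0.16 (filterByExpr by group, R 4.3.3) and were tested. Counts were scaled by TMM, and CPM values were taken over the scaled totals of these genes. The 4 groups entered one quasi-likelihood fit (glmQLFit and glmQLFTest, robust), because the constitutive MYC/Gfi1 group had only 2 libraries. The common biological coefficient of variation was 0.562, with 7 residual and a median of 3.21 prior degrees of freedom. P-values were two-sided, adjusted by Benjamini-Hochberg over the genes tested in each of the 6 comparisons, and called at 0.05. The SE of a log2 fold change was its size over the square root of its F value. A fold against a group with 0 counts in each library was taken against a floor of 3 counts over the group and is given as a lower bound. Fitted values of such genes rest on a prior count.

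Gene lists, 30 in all, were fixed before the data were examined. They covered pathways, tumour subgroups, cell types of the cerebellum and its vessels and membranes, and genes that mark RNA quality, and 649 of their 655 symbols were in the table. They were tested with camera (limma 3.58.1, preset correlation between genes of 0.01) and adjusted by Benjamini-Hochberg over the lists. Each call is given with the p from an estimated correlation, and with fry where its call is cited. Fry tests whether a list's genes move one way on balance and does not compare the list with other genes. A count adjusted over the list alone uses the edgeR p-values of its members only. With an estimated correlation, 1 of the 61 list calls was kept, that of the photoreceptor genes between the S100b-cell and the MYC/Otx2 tumours.

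The genes named were set by a rule written before the data were examined. It took the genes in the labels in every group. For the 4 main comparisons it took the 8 largest rises and the 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between libraries, leaving out numbered gene models. From each list described it took up to 4 called members with the smallest p and up to 2 members not called with the highest CPM. A selection of these is printed. Genes outside the rule are marked as chosen after their values were seen. In each called gene named in a comparison, every library of the higher group lay above every library of the lower group. Positions come from a GENCODE annotation of GRCm38, the assembly also called mm10. Ribosomal protein genes share reads with processed pseudogenes, and how the counting split such reads is not stated, so their values are uncertain.

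On simulated counts with the real means and depths, edgeR recovered 7.46% (N1ICD against S100b-cell) to 25.4% (N1ICD against MYC/Otx2) of genes changed 4-fold over the 6 comparisons. Of those changed 8-fold it recovered 33.3% (S100b-cell against MYC/Gfi1) to 45.5% (N1ICD against MYC/Otx2). False calls among 15028 unchanged genes were 5 for the N1ICD against the MYC/Otx2 tumours, 2 for the MYC/Otx2 against the MYC/Gfi1 tumours and 1 in each of the other 4. A simulated list with no change had a camera p of 0.0145 for the S100b-cell against the constitutive MYC/Gfi1 tumours. The simulation gave all groups the same dispersion per gene and drew genes independently. Groups of unequal spread and genes that move together were not covered, so these rates need not hold for the real libraries.

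Alternatives were RLE and upper-quartile factors, no filter, a filter of 10 CPM in 2 libraries, a fit of only the groups compared, thinning of each library to one depth, removal of mitochondrial, haemoglobin and ribosomal genes, the replicate number as a block, DESeq2 1.42.0, limma-voom, and leaving out each library in turn. The list tests were also run with an estimated correlation and with fry.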

Results

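Expression was profiled in 11 libraries from mouse cerebellar tumours of 4 medulloblastoma models. The constitutive MYC/Gfi1 tumours (n = 2) and the constitutive MYC/Otx2 tumours (n = 3) are models of Group 3 medulloblastoma that the series describes as published earlier. The S100b-cell tumours (n = 3) carried MYC and Gfi1 expressed in S100b-positive cells. The N1ICD tumours (n = 3) carried MYC, Gfi1 and N1ICD, the intracellular domain of the receptor Notch1, expressed in cells positive for Math1, the product of Atoh1 and a mark of granule neuron progenitors. Libraries held between 2.58 and 15.19 M counts, with the N1ICD libraries the shallowest and the S100b-cell libraries the deepest, and 14987 to 19834 genes were detected per library. Mitochondrially encoded genes took 5.98% ± 0.024 of counts (SD, n = 2) in the MYC/Gfi1 tumours and 5.41% ± 0.297 (SD, n = 3) in the MYC/Otx2 tumours. They took 16.0% ± 2.15 (SD, n = 3) in the S100b-cell tumours and 25.6% ± 2.20 (SD, n = 3) in the N1ICD tumours. These shares followed the library sets, so for mitochondrially encoded genes a difference between sets cannot be told apart from the models. Library-to-library Spearman correlations within a group had medians of 0.952 in the MYC/Otx2, 0.916 in the S100b-cell and 0.860 in the N1ICD tumours. The MYC/Gfi1 pair correlated at 0.816, close to the median of 0.814 between MYC/Gfi1 and MYC/Otx2 libraries.

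Counts at the mouse symbols of the genes named in the labels were read first. They do not check the labels, since 3′ tags count a transgene only if its 3′ end matches the mouse gene, and that end is not given in the sources used here. Myc (chromosome 15, 61985391 to 61990374, mm10), a growth-promoting transcription factor, was at 75.2 ± 48.6 CPM (SD, n = 3) in the MYC/Otx2 tumours and 19.3 ± 11.7 CPM (SD, n = 2) in the MYC/Gfi1 tumours. It was at 3.32 ± 1.16 CPM in the S100b-cell and 1.30 ± 1.03 CPM in the N1ICD tumours (SD, n = 3 each). Myc was lower in the N1ICD than in the MYC/Gfi1 tumours by a log2 change of -3.87 ± 0.77 (SE, edgeR adjusted p = 0.0154). Against the MYC/Otx2 tumours, Myc was lower in the N1ICD tumours by -5.83 ± 0.77 and in the S100b-cell tumours by -4.49 ± 0.67 (SE, edgeR adjusted p = 0.00159 and 0.00313). Gfi1 (chromosome 5, 107716657 to 107726036), a zinc finger repressor, was at 0.171 ± 0.150 CPM in the MYC/Otx2 tumours, 6.66 ± 6.35 CPM in the S100b-cell tumours and 3.43 ± 2.37 CPM in the N1ICD tumours (SD, n = 3 each). It was higher than in the MYC/Otx2 tumours in both of the latter, with log2 changes of 5.17 ± 1.16 and 4.21 ± 1.16 (SE, edgeR adjusted p = 0.0158 and 0.0289). Otx2 (chromosome 14, 48657677 to 48673819), a homeodomain factor, was at 51.0 ± 42.3 CPM (SD, n = 3) in the MYC/Otx2 tumours and passed the test in no comparison, the smallest edgeR adjusted p being 0.0615. Notch1 (chromosome 2, 26457903 to 26516663) had at most 7 counts in any library. Atoh1 was not tested, with 8 counts in MYC/Gfi1 replicate 1, 5 and 1 in S100b-cell replicates 1 and 2, and 0 in the other libraries. S100b, a calcium-binding protein of glia, was at 291 ± 376 CPM (SD, n = 2) in the MYC/Gfi1 tumours and 30.9 ± 31.4 CPM (SD, n = 3) in the S100b-cell tumours, a difference that did not pass (edgeR adjusted p = 0.218).

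The N1ICD tumours were compared with the constitutive MYC/Gfi1 tumours, which share MYC and Gfi1 but not N1ICD or the restriction to Math1-positive cells. Notch target genes were among the genes that rose. Heyl (chromosome 4, 123233556 to 123249875), a transcriptional repressor induced by Notch, was at 109 ± 32.3 CPM (SD, n = 3) against 0.859 ± 0.599 CPM (SD, n = 2), a log2 rise of 6.93 ± 0.82 (SE, edgeR adjusted p = 0.00294). Ccnd1, which encodes cyclin D1, rose from 7.34 ± 3.8 to 256 ± 81.6 CPM, or 5.12 ± 0.68 log2 (edgeR adjusted p = 0.00477). Some neuronal genes fell, among them Camk2b, a calcium-dependent kinase subunit, from 174 ± 141 to 4.64 ± 2.63 CPM, and the synaptic vesicle gene Syp, from 44.7 ± 33.1 to 1.07 ± 1.18 CPM. Some genes of vessel walls rose, such as the smooth muscle actin gene Acta2, from 10.2 ± 5.51 to 1276 ± 1281 CPM.

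Of the 15 measured Notch targets, 5 rose (Heyl, Ccnd1, Hey2, Notch3 and, named after its values were seen, Nrarp) and 10 did not pass, and 8 were higher when adjusted over the list alone. Hey2 reached 83.1 ± 19.5 CPM and Notch3, a Notch receptor, 76.9 ± 58.1 CPM (SD, n = 3 each), against 0.757 ± 0.249 and 2.30 ± 0.447 CPM (SD, n = 2 each). Hes5, another Notch-induced repressor, was at 596 ± 722 CPM against 13.0 ± 7.23 CPM and did not pass (edgeR adjusted p = 0.0659). The list's median log2 change was 3.43. For the Notch targets, the camera adjusted p was 1.81e-04, and adjusted p = 0.570 with an estimated correlation, the highest of 19 alternatives whose lowest was 1.03e-06. In the list of neuronal differentiation genes, 13 of 35 fell, 27 were lower when adjusted over the list alone, and the median was -5.24. For the neuronal genes, the camera adjusted p was 3.07e-10, and adjusted p = 0.570 with an estimated correlation (lowest alternative 1.37e-14). Chga, a granin of secretory vesicles, fell from 36.2 ± 16.8 to 0.627 ± 0.363 CPM. Among mature granule cell genes, 7 of 12 fell and 11 were lower when adjusted over the list alone, including Rbfox3, the neuronal nuclear antigen gene, from 292 ± 332 to 4.65 ± 3.24 CPM. For the mature granule cell genes, the camera adjusted p was 1.24e-04, and adjusted p = 0.570 with an estimated correlation (lowest alternative 5.69e-07). These 3 list calls held without each library in turn, but without MYC/Gfi1 replicate 2 the neuronal genes called lower went from 13 to 2 and their median to -2.74. The 7 called mature granule cell genes were all lost without that library, and their median went from -6.65 to -2.70 (camera adjusted p = 0.0464). In each list of the report given with its lowest alternative, the estimated correlation gave the highest adjusted p. MYC/Gfi1 replicate 2 stood apart in these genes: Cbln3, Gabra6 and Pvalb, chosen after their values were seen, were at 1159, 446 and 482 CPM there against 2.10, 0.932 and 2.91 CPM in replicate 1.

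**Figure D1:**
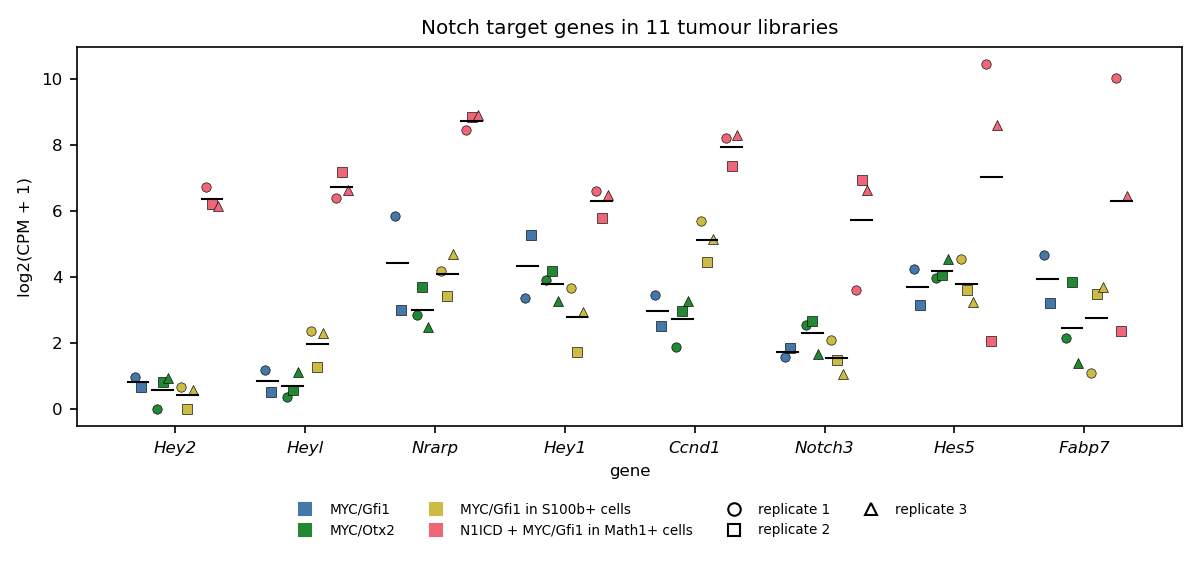
Log2(CPM + 1) of 8 Notch target genes in the 11 libraries, coloured by model, with a symbol per replicate number and a bar at each group's mean. Hey2, Heyl and Nrarp were high in each N1ICD library, at 70.2 to 105.5, 82.7 to 145 and 354 to 477 CPM, whereas Hes5 and Fabp7 were at 3.14 and 4.18 CPM in N1ICD replicate 2 against 1399 and 1058 CPM in replicate 1; Hey1 was chosen after its values were seen.

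Of 22 endothelial and pericyte genes, 6 rose and 8 were higher when adjusted over the list alone. For the endothelial and pericyte genes, the camera adjusted p was 0.00445, and adjusted p = 0.570 with an estimated correlation (lowest alternative 4.17e-04). They included Kcnj8, a potassium channel subunit of pericytes (28.5 ± 28.8 against 0.334 ± 0.143 CPM), the contractile gene Tagln (33.4 ± 13.9 against 1.32 ± 0.435 CPM) and the receptor gene Pdgfrb (106 ± 87.8 against 5.70 ± 3.44 CPM). Acta2 was at 24.9 CPM in N1ICD replicate 1 and 2584 and 1219 CPM in replicates 2 and 3, a spread wider than that of Heyl or Hey2. Of 9 mitochondrially encoded genes, 6 rose and all 9 were higher when adjusted over the list alone, led by the ribosomal RNA gene mt-Rnr2 with 3.27 ± 0.24 log2. For the mitochondrially encoded genes, the camera adjusted p was 2.41e-06, and adjusted p = 0.405 with an estimated correlation (lowest alternative 1.19e-06). Among 40 cell cycle genes, 10 rose and 13 were higher and 1 lower when adjusted over the list alone, with Mki67, the Ki-67 proliferation antigen, at 226 ± 58.6 against 42.3 ± 22.2 CPM. For the cell cycle genes, the camera adjusted p was 8.65e-04, and adjusted p = 0.736 with an estimated correlation (lowest alternative 1.75e-07). Genes of myelin and microglia fell in part: 6 of 16 oligodendrocyte lineage genes fell and 1 rose, with the myelin gene Mbp down from 216 ± 43.3 to 24.9 ± 7.37 CPM, and 4 of 24 microglial genes fell, with C1qc, a complement subunit, down from 67.5 ± 18.2 to 13.7 ± 3.62 CPM. Adjusted over the list alone the counts were 8 lower and 1 higher for the former and 6 lower and 1 higher for the latter (camera adjusted p = 0.00445 and 0.00730, and adjusted p = 0.578 and 0.721 with an estimated correlation; lowest alternatives 6.03e-04 and 7.21e-05).

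Camera also called the MYC targets, 10 higher and 1 lower of 54, and the lymphocyte, granule cell progenitor and interferon genes (camera adjusted p = 0.0182, 2.84e-04, 0.00386 and 0.0451, and adjusted p = 0.795, 0.570, 0.721 and 0.795 with an estimated correlation). Among members, edgeR called 2 of 14 lymphocyte and 2 of 20 granule cell progenitor genes lower, and 0 of 24 interferon genes.

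The largest rises included genes with no count in either MYC/Gfi1 library. Olfr558, an olfactory receptor gene, was at least 1292-fold higher, Rasl12, a Ras-like gene, at least 242-fold, and Tnnt3, a troponin gene, at least 215-fold. Tal1, a transcription factor of blood and endothelium, rose from 0.290 ± 0.411 to 162 ± 145 CPM. The largest falls were led by immunoglobulin genes with no count in any N1ICD library, Igha (at least 4741-fold lower), Ighg2c (at least 3388-fold) and Igkc (at least 757-fold), and by Slc24a2, a sodium/calcium exchanger gene (at least 106-fold). Across all genes, edgeR called 1754 of 15228, 833 higher and 921 lower, and 4601 had an unadjusted p under 0.05. The libraries of the groups did not overlap in 5789 genes, or 38.0%, where chance gives 20%. The count was 805 without MYC/Gfi1 replicate 2, 797 and 883 without N1ICD replicates 2 and 3, 15 in a fit of these groups alone, 3369 with DESeq2 and 1014 with limma-voom, whose split was 62.0% higher against 47.5%. Without MYC/Gfi1 replicate 2 the cell cycle genes called higher went from 10 to 2 and their median from 0.48 to 0.052, and the oligodendrocyte genes called lower went from 6 to 1 and their median from -2.85 to -0.65. Both of these list calls were lost there (camera adjusted p = 0.354 and 0.115), the endothelial call without MYC/Gfi1 replicate 1 and the microglial call without N1ICD replicate 1. Lost as well were the MYC target call (MYC/Gfi1 replicate 2, with 2 genes higher and 3 lower and a median of 0.12 in place of 0.34, or N1ICD replicate 3), the granule cell progenitor call (replicate 2 of either group) and the interferon call (MYC/Gfi1 replicate 2 or N1ICD replicate 1 or 3).

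**Figure D2:**
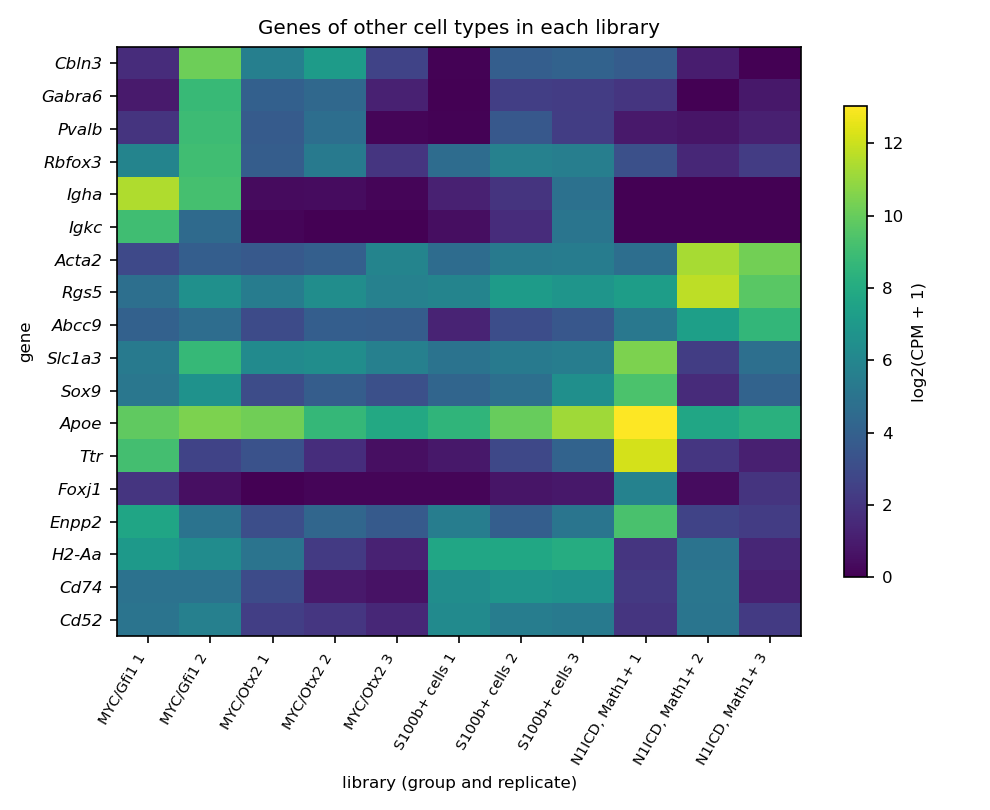
Log2(CPM + 1) per library (columns, by model) of 18 genes marking granule cells and neurons, plasma cells, mural cells, astroglia, choroid plexus and ependyma, and antigen-presenting cells (rows), some of them chosen after their values were seen. Cbln3 was at 1159 CPM in MYC/Gfi1 replicate 2, Acta2 at 2584 and 1219 CPM in N1ICD replicates 2 and 3, and Slc1a3 and Ttr at 1402 and 4672 CPM in N1ICD replicate 1.

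The S100b-cell tumours were compared with the constitutive MYC/Gfi1 tumours, which share the oncogenes and differ in the cells that express them. Dkc1, a nucleolar pseudouridine synthase gene, rose from 460 ± 32.1 CPM (SD, n = 2) to 1453 ± 239 CPM (SD, n = 3), or 1.66 ± 0.24 log2 (SE, edgeR adjusted p = 0.0131), and Hmgb2, a chromatin protein of dividing cells, rose from 29.3 ± 12.7 to 145 ± 6.30 CPM, or 2.31 ± 0.30 log2 (edgeR adjusted p = 0.0112). The neuronal gene Syp fell from 44.7 ± 33.1 to 1.90 ± 1.59 CPM, or -4.54 ± 0.88 log2 (edgeR adjusted p = 0.0271). Sox3 and Sox1, transcription factors of neural progenitors, fell from 125 ± 72.8 and 56.7 ± 53.2 CPM to 0.275 ± 0.274 and 0.261 ± 0.0608 CPM.

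Of 54 MYC target genes, 7 rose and 18 were higher and 1 lower when adjusted over the list alone, with a median of 0.68. For the MYC targets, the camera adjusted p was 1.16e-07, and adjusted p = 0.797 with an estimated correlation (lowest alternative 2.03e-09). Nop58 and Ddx21, which act in ribosome assembly, rose by 2.14 ± 0.34 and 2.02 ± 0.38 log2. Of 40 cell cycle genes, 4 rose and 8 were higher when adjusted over the list alone, including the cyclin gene Ccne2 at 55.9 ± 2.76 against 19.4 ± 6.05 CPM. For the cell cycle genes, the camera adjusted p was 5.12e-04, and adjusted p = 0.804 with an estimated correlation (lowest alternative 1.79e-07). Among 35 neuronal genes, 3 fell (Syp, Chga and Camk2b) and 16 were lower when adjusted over the list alone, with a median of -3.61. For the neuronal genes, the camera adjusted p was 3.00e-12, and adjusted p = 0.797 with an estimated correlation (lowest alternative 2.73e-20). Without MYC/Gfi1 replicate 2, the library high in Cbln3, these 3 genes and the 7 called MYC targets lost their calls. Both lists still passed there, with the neuronal median going from -3.61 to -1.21 and the MYC target median from 0.68 to 0.46 (camera adjusted p = 1.66e-05 and 0.00668). The mitochondrially encoded list had 7 of 9 members higher, and all 9 when adjusted over the list alone, led by mt-Nd2 with 2.50 ± 0.28 log2. For the mitochondrially encoded genes, the camera adjusted p was 5.47e-08, and adjusted p = 0.246 with an estimated correlation (lowest alternative 4.07e-08). It was the 1 list of this comparison that also passed with fry. Between the constitutive groups, whose libraries share a naming style, its median was -0.10 and 0 of 9 members were called. A difference between library sets cannot be told apart from the models for this list, here or in the other comparisons across sets. Of 46 ribosomal protein genes, 3 rose and 13 were higher when adjusted over the list alone. For the ribosomal protein genes, the camera adjusted p was 2.71e-08, and adjusted p = 0.797 with an estimated correlation (lowest alternative 1.31e-17). They were Rpl26 (chromosome 11, 68901583 to 68906989), with 5.50 ± 0.35 log2 (edgeR adjusted p = 2.60e-04), Rps14, with 2.57 ± 0.28, and Rpl6, with 1.03 ± 0.22, and all are uncertain because of reads shared with pseudogenes.

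Camera also called the mature granule cell, Purkinje cell and oligodendrocyte lists lower, with medians of -4.12, -4.54 and -1.90 (camera adjusted p = 4.35e-04, 0.0129 and 0.00448, and adjusted p = 0.797 with an estimated correlation in each). The astroglial and granule cell progenitor lists were called lower as well (camera adjusted p = 0.00548 and 0.00552, and adjusted p = 0.804 and 0.797 with an estimated correlation). These 5 calls were lost without MYC/Gfi1 replicate 2, where the medians of the first 3 were -0.67, 0.22 and -1.08, the Purkinje cell median turning sign. The Purkinje cell and granule cell progenitor calls were also lost without S100b-cell replicate 1. With all libraries, edgeR called 0 of 12 mature granule cell, 0 of 13 Purkinje cell, 1 of 16 oligodendrocyte, 0 of 35 astroglial and 0 of 20 granule cell progenitor genes. Adjusted over the list alone, 9, 8, 2, 0 and 0 were lower.

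Other large rises were those of Twist2, a mesenchymal transcription factor gene (at least 136-fold), and of Cdk6, a cell cycle kinase gene (4.03 ± 0.79 log2). Igha fell from 1730 ± 1616 to 10.7 ± 14.8 CPM, and the neuronal genes Nptxr and Rasgrf1 fell by 6.30 and by 6.17 on the log2 scale. Over all genes, edgeR called 663, 357 higher and 306 lower, and 3602 had an unadjusted p under 0.05. Groups did not overlap in 6293 genes, or 41.3%, where chance gives 20%. In a fit of these groups alone edgeR called 0 genes, with 3287 at an unadjusted p under 0.05, while DESeq2 called 2306 and limma-voom 1392, and the share called higher, 53.8%, was 44.6% with RLE and 62.6% with upper-quartile factors. The count was 1995 and 61 without MYC/Gfi1 replicates 1 and 2, 12, 137 and 55 without S100b-cell replicates 1, 2 and 3, 337, 305 and 285 without MYC/Otx2 replicates 1, 2 and 3 and 1076 without N1ICD replicate 1, and the cell cycle and ribosomal calls were lost without MYC/Gfi1 replicate 2 (camera adjusted p = 0.439 and 0.291), where 1 cell cycle gene and 2 ribosomal genes were called higher and the medians went from 0.52 and 0.59 to 0.21 and 0.18.

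**Figure D3:**
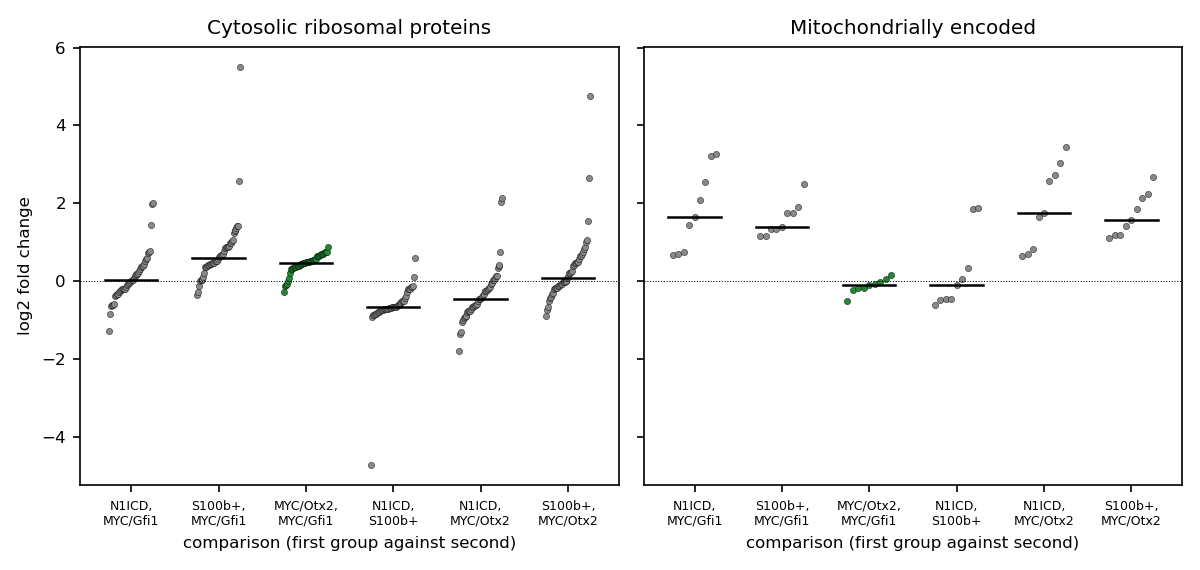
Log2 fold change of each of the 46 ribosomal protein genes and the 9 mitochondrially encoded genes in the 6 comparisons, with a line at each median and in green the comparison whose libraries share a naming style, MYC/Otx2 against MYC/Gfi1. The SD over the ribosomal genes was 0.251 there and 0.889 for the S100b-cell against the MYC/Gfi1 tumours, or 0.534 without Rpl26.

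The N1ICD tumours were compared with the S100b-cell tumours, the other model made for the series. Hey2 (chromosome 10, 30832359 to 30842801), a repressor induced by Notch, was at 83.1 ± 19.5 CPM against 0.350 ± 0.309 CPM (SD, n = 3 each), a log2 rise of 7.83 ± 1.04 (SE, edgeR adjusted p = 0.0151). Heyl rose by 5.11 ± 0.61 and Nrarp, a feedback inhibitor of Notch (chromosome 2, 25180758 to 25183339), by 4.64 ± 0.73 log2 (edgeR adjusted p = 0.00880 and 0.0227). Kcnj3, a potassium channel gene of excitable cells, fell from 73.5 ± 22.4 to 1.18 ± 0.399 CPM, or -5.95 ± 0.47 log2 (edgeR adjusted p = 7.36e-04). Ptger3, a prostaglandin receptor gene, was at 26.3 ± 8.91 CPM in the S100b-cell tumours and had no count in any N1ICD library, at least 67.7-fold lower.

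Of the 15 Notch targets, 6 rose (the 5 named in the comparison with the constitutive MYC/Gfi1 tumours and, named after its values were seen, Hey1) and 9 were higher when adjusted over the list alone, with a median of 3.53. For the Notch targets, the camera adjusted p was 3.23e-10, and adjusted p = 0.203 with an estimated correlation (lowest alternative 2.02e-14). The call held without each library in turn and with fry (adjusted p = 0.00629). Hes5 was at 596 ± 722 against 14.0 ± 7.45 CPM and Fabp7, a radial glia gene, at 383 ± 586 against 7.74 ± 5.81 CPM, and neither passed (edgeR adjusted p = 0.101 and 0.133). Among 22 endothelial and pericyte genes, 1 rose, Abcc9, a channel subunit of pericytes, at 196 ± 178 against 6.55 ± 4.62 CPM, and 10 were higher when adjusted over the list alone. For the endothelial and pericyte genes, the camera adjusted p was 2.87e-06, and adjusted p = 0.387 with an estimated correlation (lowest alternative 1.33e-07). Rgs5, a pericyte gene, was at 151, 3409 and 822 CPM in N1ICD replicates 1, 2 and 3 against 57.6 to 143 CPM in the S100b-cell libraries. Of 24 microglial genes, 1 fell, C1qc, from 58.8 ± 7.42 to 13.7 ± 3.62 CPM, and 7 were lower when adjusted over the list alone. For the microglial genes, the camera adjusted p was 4.98e-04, and adjusted p = 0.909 with an estimated correlation (lowest alternative 3.32e-06). Of 46 ribosomal protein genes, 1 fell, Rpl26, by 4.72 ± 0.28 log2, and 7 were lower when adjusted over the list alone. For the ribosomal protein genes, the camera adjusted p was 5.08e-06, and adjusted p = 0.909 with an estimated correlation (lowest alternative 2.92e-09). The metallothionein gene Mt2 of the astroglial list fell from 790 ± 225 to 98.0 ± 46.2 CPM while the list's median was 1.70. For the astroglial genes, the camera adjusted p was 0.0449, and adjusted p = 0.909 with an estimated correlation (lowest alternative 5.96e-05). Adjusted over that list alone, 4 of its 35 genes were higher and 1 lower, and its call was lost without any 1 of 4 libraries, the direction turning without N1ICD replicate 1 (camera adjusted p = 0.875).

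The lymphocyte list was called lower, with a median of -2.19, or -1.90 with genes absent from a group at their bounds (camera adjusted p = 7.23e-07, and adjusted p = 0.470 with an estimated correlation). Camera also called the MYC targets and the interferon genes lower and the choroid plexus genes higher, the last with a median of 3.66 (camera adjusted p = 0.00199, 4.98e-04 and 0.0225, and adjusted p = 0.909 with an estimated correlation in each). In these lists 0 of 14 lymphocyte, 0 of 54 MYC target, 0 of 24 interferon and 0 of 11 choroid plexus genes were called by edgeR. Adjusted over the list alone, 2 choroid plexus genes were higher and no gene of the other lists passed. The choroid plexus call was lost without S100b-cell replicate 1 or N1ICD replicate 1, the MYC target call without N1ICD replicate 1 and the interferon call without N1ICD replicate 3.

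Tal1 was at 162 ± 145 against 0.486 ± 0.192 CPM, and Gjc1, a gap junction gene of vascular smooth muscle, at 293 ± 170 against 2.46 ± 0.681 CPM. Bmp4, a growth factor of the BMP family, fell from 62.9 ± 27.3 to 1.46 ± 1.08 CPM, and Ptgis, prostacyclin synthase, from 86.3 ± 63.8 to 1.85 ± 1.56 CPM. Over all genes edgeR called 185, of which 62 were lower and the others higher, with 2844 at an unadjusted p under 0.05 and no overlap between libraries in 3979 genes, or 26.1%, where chance gives 10%. The count was 83 in a fit of these groups alone and 1360 with DESeq2, while limma-voom called 127, 86.6% of them higher against 66.5%. It was 106, 18 and 9 without S100b-cell replicates 1, 2 and 3, 84, 79 and 91 without MYC/Otx2 replicates 1, 2 and 3, 283 without MYC/Gfi1 replicate 2 and 111 without N1ICD replicate 3, and the microglial call was lost without N1ICD replicate 1.

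The constitutive MYC/Otx2 and MYC/Gfi1 tumours, whose labels share a naming style, differ in the oncogene paired with MYC. Some genes of photoreceptors rose in the MYC/Otx2 tumours. Sag, the rod arrestin gene (chromosome 1, 87803680 to 87845158), was at 97.3 ± 64.9 CPM (SD, n = 3) against 1.05 ± 0.661 CPM (SD, n = 2), a log2 rise of 6.49 ± 0.84 (SE, edgeR adjusted p = 0.00871). Gnb3 (chromosome 6, 124834240 to 124840275), Gngt2 and Gnat2, subunits of cone transducin, rose by 7.17 ± 1.16, 4.05 ± 0.55 and 4.84 ± 0.83 log2 (edgeR adjusted p = 0.0142, 0.00999 and 0.0172). Vsx1, a homeobox gene of retinal bipolar cells, was at 60.4 ± 4.92 CPM with no count in either MYC/Gfi1 library, at least 313-fold higher, and Grm6, a glutamate receptor gene of bipolar cells, was at least 233-fold higher. Across all genes the median log2 change was -0.14, so values lie that far below a scale centred on the median gene.

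Of 34 photoreceptor genes listed, only 16 were tested. Of these 16, 8 rose and 10 were higher when adjusted over the list alone. Their median was 4.89, or 4.75 with genes absent from a group set at their bounds. A gene could pass the low-count filter through the MYC/Otx2 libraries alone, so the share that rose and the median may favour such genes. The list passed with camera (adjusted p = 1.24e-08, and adjusted p = 0.0519 with an estimated correlation; lowest alternative 1.97e-09), with fry (adjusted p = 1.51e-04) and without each library in turn. Crx, a photoreceptor transcription factor gene outside the naming rule and chosen after its values were seen, was at 4.10, 9.72 and 7.63 CPM in the MYC/Otx2 libraries and had no count in the MYC/Gfi1 libraries. Of 54 MYC target genes, 5 rose and 16 were higher when adjusted over the list alone, including Rcl1, which acts in ribosomal RNA processing (2.15 ± 0.25 log2), and Cad, of pyrimidine synthesis (1.37 ± 0.25 log2). For the MYC targets, the camera adjusted p was 3.03e-10, and adjusted p = 0.668 with an estimated correlation (lowest alternative 1.27e-12). Of 40 cell cycle genes, 3 rose and 9 were higher when adjusted over the list alone, among them the mitotic genes Cdca8 and Nusap1 with 1.27 ± 0.31 and 1.33 ± 0.33 log2. For the cell cycle genes, the camera adjusted p was 3.03e-10, and adjusted p = 0.668 with an estimated correlation (lowest alternative 3.14e-13).

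**Figure D4:**
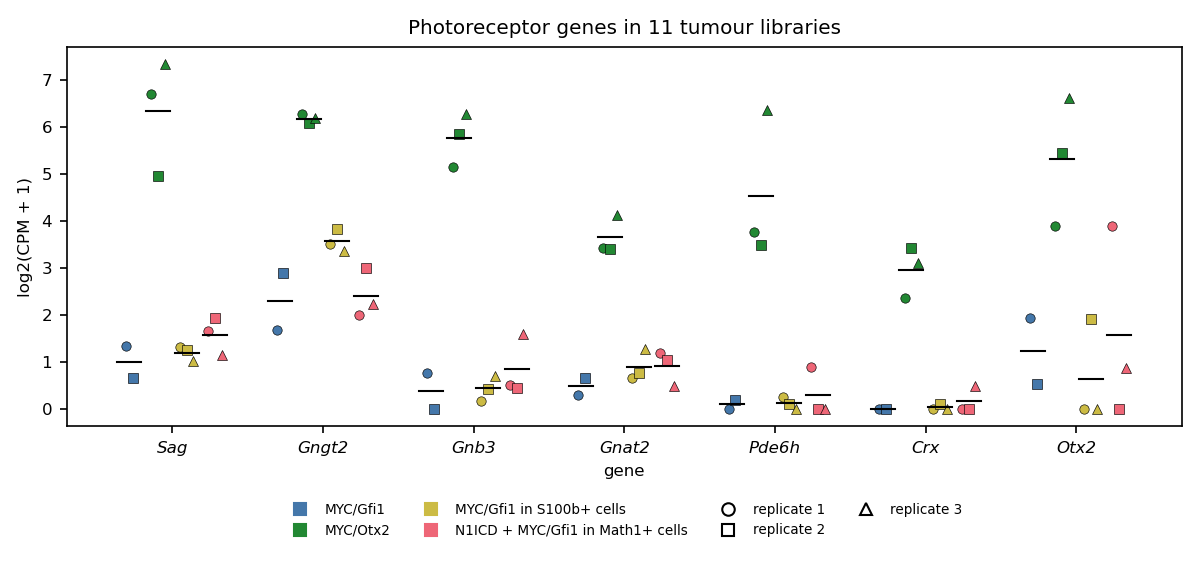
Log2(CPM + 1) of 6 photoreceptor genes and Otx2 in the 11 libraries, coloured by model, with a symbol per replicate number and a bar at each group's mean. Sag, Gngt2, Gnb3 and Gnat2 were higher in each MYC/Otx2 library than in any other library, with Gngt2 at 71.2 ± 4.67 CPM (SD, n = 3); Crx and Otx2 are shown for their levels, and Otx2 passed the test in no comparison.

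Of 14 lymphocyte genes, 4 fell and 8 were lower when adjusted over the list alone, with a median of -5.51, or -3.70 with genes absent from a group at their bounds. For the lymphocyte genes, the camera adjusted p was 3.31e-05, and adjusted p = 0.668 with an estimated correlation (lowest alternative 1.36e-06). The leukocyte surface gene Cd52 fell from 41.0 ± 14.0 to 3.12 ± 1.33 CPM and the B cell receptor gene Cd79b was at least 25.1-fold lower. Of 24 interferon and antigen presentation genes, 1 fell, Ifitm3, from 157 ± 78.5 to 18.9 ± 8.70 CPM, and 2 were lower when adjusted over the list alone. For the interferon and antigen presentation genes, the camera adjusted p was 2.58e-05, and adjusted p = 0.668 with an estimated correlation (lowest alternative 4.77e-08). In the list of immediate early and heat shock genes, 4 of 21 fell (Jund, Egr2, Dusp1 and Jun) and 8 were lower when adjusted over the list alone, with Jund, a transcription factor gene of the AP-1 family, at -3.12 ± 0.49 log2. For the immediate early and heat shock genes, the camera adjusted p was 0.00543, and adjusted p = 0.668 with an estimated correlation (lowest alternative 0.00183). Of 35 astroglial genes, 2 fell, the metallothionein genes Mt1 (-3.14 ± 0.46 log2) and Mt2 (-3.17 ± 0.49 log2), and 3 were lower when adjusted over the list alone. For the astroglial genes, the camera adjusted p was 1.86e-04, and adjusted p = 0.668 with an estimated correlation (lowest alternative 4.13e-07). Neuronal genes had 2 of 35 members lower, Camk2b and Chga, and 21 when adjusted over the list alone. For the neuronal genes, the camera adjusted p was 2.04e-06, and adjusted p = 0.668 with an estimated correlation (lowest alternative 2.81e-08).

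Without MYC/Gfi1 replicate 2 these 2 neuronal genes, the 3 cell cycle genes and the 4 lymphocyte genes lost their calls, and 1 MYC target was called in place of 5. These 4 lists still passed there, with medians going from -3.60, 1.02, -5.51 and 0.76 to -1.33, 0.66, -5.30 and 0.48 (camera adjusted p = 0.0290, 2.00e-04, 2.23e-06 and 9.94e-05). Camera also called the ribosomal protein genes higher and the microglial and granule cell progenitor genes lower (camera adjusted p = 5.69e-06, 0.0320 and 0.0320, and adjusted p = 0.668 with an estimated correlation in each), and all 3 calls were lost without MYC/Gfi1 replicate 2. The microglial and granule cell progenitor calls were also lost without MYC/Otx2 replicate 3, and the microglial call without MYC/Gfi1 replicate 1. With all libraries, edgeR called 0 of 46 ribosomal protein, 1 of 24 microglial and 1 of 20 granule cell progenitor genes.

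Sohlh1, a germ cell transcription factor gene, was at least 1944-fold higher in the MYC/Otx2 tumours, at 382 ± 229 CPM, and Crabp1, a retinoic acid binding protein gene, at least 287-fold higher. Lin28a, an RNA-binding protein of early development, was at 75.6 ± 37.7 CPM in the MYC/Gfi1 tumours and at least 576-fold lower, and Tmprss13, a protease gene, at least 747-fold lower. Igha was at 0.257 ± 0.131 CPM against 1730 ± 1616 CPM. Over all genes edgeR called 832, 370 higher and 462 lower, with 4302 at an unadjusted p under 0.05 and no overlap between libraries in 6646 genes, or 43.6%, where chance gives 20%. The count was 365 in a fit of these groups alone, 2695 with DESeq2 and 1377 with limma-voom. It was 2170 and 218 without MYC/Gfi1 replicates 1 and 2, 87, 232 and 65 without MYC/Otx2 replicates 1, 2 and 3, 409 and 382 without S100b-cell replicates 2 and 3 and 1401 without N1ICD replicate 1.

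Between the N1ICD and the MYC/Otx2 tumours edgeR called 3315 genes, 1829 higher and 1486 lower, around a median log2 change of 0.14 over all genes. Heyl, Ccnd1, Nrarp and Hey2 rose by 7.34 ± 0.69, 5.39 ± 0.58, 5.83 ± 0.78 and 7.14 ± 1.02 log2 (SE, edgeR adjusted p = 5.38e-04, 7.25e-04, 0.00170 and 0.00213, n = 3 each). Some photoreceptor genes fell, with Sag going from 97.3 ± 64.9 to 2.05 ± 0.790 CPM and Gngt2 from 71.2 ± 4.67 to 4.54 ± 2.13 CPM (SD, n = 3 each). Hes6, a gene of neurogenesis, fell from 233 ± 66.2 to 26.0 ± 8.03 CPM, and Jag1, a Notch ligand, rose from 6.47 ± 3.86 to 194 ± 166 CPM.

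Of 15 Notch targets, 10 rose and 11 were higher when adjusted over the list alone, with a median of 5.08, or 4.76 with genes absent from a group at their bounds. For the Notch targets, the camera adjusted p was 2.49e-05, and adjusted p = 0.333 with an estimated correlation (lowest alternative 3.23e-07). Of the 16 photoreceptor genes tested, out of 34 listed, 9 fell and 11 were lower when adjusted over the list alone. For the photoreceptor genes, the camera adjusted p was 3.12e-07, and adjusted p = 0.0720 with an estimated correlation (lowest alternative 5.22e-08). Among 15 Notch ligands and proneural factors, 5 fell and 1 rose, and 6 were lower and 2 higher when adjusted over the list alone, with Neurod4, a proneural factor gene, at least 75.6-fold lower. For the Notch ligands and proneural factors, the camera adjusted p was 0.00907, and adjusted p = 0.333 with an estimated correlation (lowest alternative 0.00173). Of 22 endothelial and pericyte genes, 10 rose and 12 were higher when adjusted over the list alone, with Tagln at 33.4 ± 13.9 against 0.154 ± 0.267 CPM. For the endothelial and pericyte genes, the camera adjusted p was 2.20e-04, and adjusted p = 0.333 with an estimated correlation (lowest alternative 1.18e-05). Mitochondrially encoded genes had 8 of 9 members higher, and all 9 when adjusted over the list alone, with mt-Rnr2 up by 3.45 ± 0.20 log2. For the mitochondrially encoded genes, the camera adjusted p was 9.50e-06, and adjusted p = 0.254 with an estimated correlation (lowest alternative 9.14e-06). The intermediate filament genes Vim and Nes of the astroglial list rose by 4.48 ± 0.66 and 5.35 ± 0.95 log2, and in that list 10 of 35 genes rose and 2 fell, and 14 were higher and 2 lower when adjusted over the list alone. For the astroglial genes, the camera adjusted p was 0.0278, and adjusted p = 0.872 with an estimated correlation (lowest alternative 1.82e-04). Of 21 fibroblast and matrix genes, 6 rose and 2 fell, and 8 were higher and 2 lower when adjusted over the list alone, with the matrix gene Sparc up by 3.99 ± 0.73 and the growth factor gene Igf2 by 5.52 ± 1.24 log2. For the fibroblast and matrix genes, the camera adjusted p was 0.0325, and adjusted p = 0.610 with an estimated correlation (lowest alternative 0.00956). Immediate early and heat shock genes had 9 of 21 members higher, and 9 higher and 1 lower when adjusted over the list alone. For this list, the camera adjusted p was 0.0211, and adjusted p = 0.601 with an estimated correlation (lowest alternative 0.00683). Camera also called the MYC targets, 4 higher and 12 lower of 54, and the mature granule cell, neuronal and ribosomal protein genes lower (camera adjusted p = 0.00894, 0.0204, 0.0274 and 0.0278, and adjusted p = 0.872 with an estimated correlation in each). Among members, edgeR called 1 of 12 mature granule cell and 1 of 35 neuronal genes lower, and 2 of 46 ribosomal protein genes higher and 6 lower.

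Over all genes, 5665 had an unadjusted p under 0.05 and 6323, or 41.5%, showed no overlap between libraries, where chance gives 10%. The count was 1654, 1864 and 1712 without MYC/Otx2 replicates 1, 2 and 3. The astroglial call was lost without MYC/Otx2 replicate 3 or N1ICD replicate 1, the fibroblast and immediate early calls without N1ICD replicate 2, and the proneural call under the stricter filter. Lost as well were the MYC target call (N1ICD replicate 1), the mature granule cell and neuronal calls (replicate 2 of either group) and the ribosomal call (MYC/Otx2 replicate 1 or 3 or N1ICD replicate 2).

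The S100b-cell tumours were also compared with the MYC/Otx2 tumours, with a median log2 change of 0.17 over all genes. Some photoreceptor genes fell, among them Sag from 97.3 ± 64.9 to 1.30 ± 0.248 CPM, Gnb3 from 55.6 ± 20.8 to 0.367 ± 0.249 CPM and Pde6h, a cone phosphodiesterase subunit, from 34.4 ± 39.9 to 0.0877 ± 0.0984 CPM (SD, n = 3 each). Among antigen presentation genes, H2-Eb1 and Cd74, of the class II pathway, rose from 1.06 ± 0.796 and 2.74 ± 3.50 CPM to 95.2 ± 18.0 and 97.4 ± 13.0 CPM (edgeR adjusted p = 0.0138 and 0.0202). Ifitm3, an interferon-induced membrane protein, rose by 5.03 ± 0.77 log2, and B2m, the light chain of class I molecules, by 2.81 ± 0.67 log2 (SE, edgeR adjusted p = 0.00370 and 0.0208).

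Of the 16 photoreceptor genes tested, out of 34 listed, 10 fell and 13 were lower when adjusted over the list alone. Their median was -4.84. For the photoreceptor genes, the camera adjusted p was 4.14e-10, and adjusted p = 0.0282 with an estimated correlation, the highest of 19 alternatives. Of 24 interferon and antigen presentation genes, 6 rose and 11 were higher when adjusted over the list alone. For the interferon and antigen presentation genes, the camera adjusted p was 3.02e-05, and adjusted p = 0.935 with an estimated correlation (lowest alternative 9.90e-08). Of 14 lymphocyte genes, 5 rose and 11 were higher when adjusted over the list alone, Cd52 among them at 53.1 ± 18.0 against 3.12 ± 1.33 CPM. For the lymphocyte genes, the camera adjusted p was 1.02e-04, and adjusted p = 0.580 with an estimated correlation (lowest alternative 3.78e-06). Immediate early and heat shock genes had 6 of 21 members higher, also 6 when adjusted over the list alone, with Jund, Jun and Atf3 up by 3.15 ± 0.46, 3.29 ± 0.54 and 3.54 ± 0.60 log2 and the chaperone gene Hsp90aa1 by 1.79 ± 0.23 log2. For the immediate early and heat shock genes, the camera adjusted p was 0.00633, and adjusted p = 0.580 with an estimated correlation (lowest alternative 0.00235). All 9 mitochondrially encoded genes rose, mt-Nd2 by 2.68 ± 0.24 log2, and all 9 were higher when adjusted over the list alone. For the mitochondrially encoded genes, the camera adjusted p was 6.47e-06, and adjusted p = 0.238 with an estimated correlation (lowest alternative 1.31e-06). Among 40 cell cycle genes, 3 rose and 4 fell, with Hmgb2 up by 1.73 ± 0.26 and Cdca8 changed by -1.55 ± 0.27 log2, and 3 were higher and 8 lower when adjusted over the list alone. For the cell cycle genes, the camera adjusted p was 0.0146, and adjusted p = 0.935 with an estimated correlation (lowest alternative 3.49e-04). Of 15 Notch ligands and proneural factors, 4 fell, also 4 when adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.580 with an estimated correlation), and the call was lost without any 1 of 7 libraries.

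Over all genes edgeR called 2727, 1526 higher and 1201 lower, with 5308 at an unadjusted p under 0.05 and no overlap between libraries in 7669 genes, or 50.4%, where chance gives 10%. The count was 4622 in a fit of these groups alone and 4327 with DESeq2, and 1302, 1285 and 1192 without MYC/Otx2 replicates 1, 2 and 3 and 1750, 1330 and 1197 without S100b-cell replicates 1, 2 and 3. The cell cycle call was lost without S100b-cell replicate 2 or 3.

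**Figure D5:**
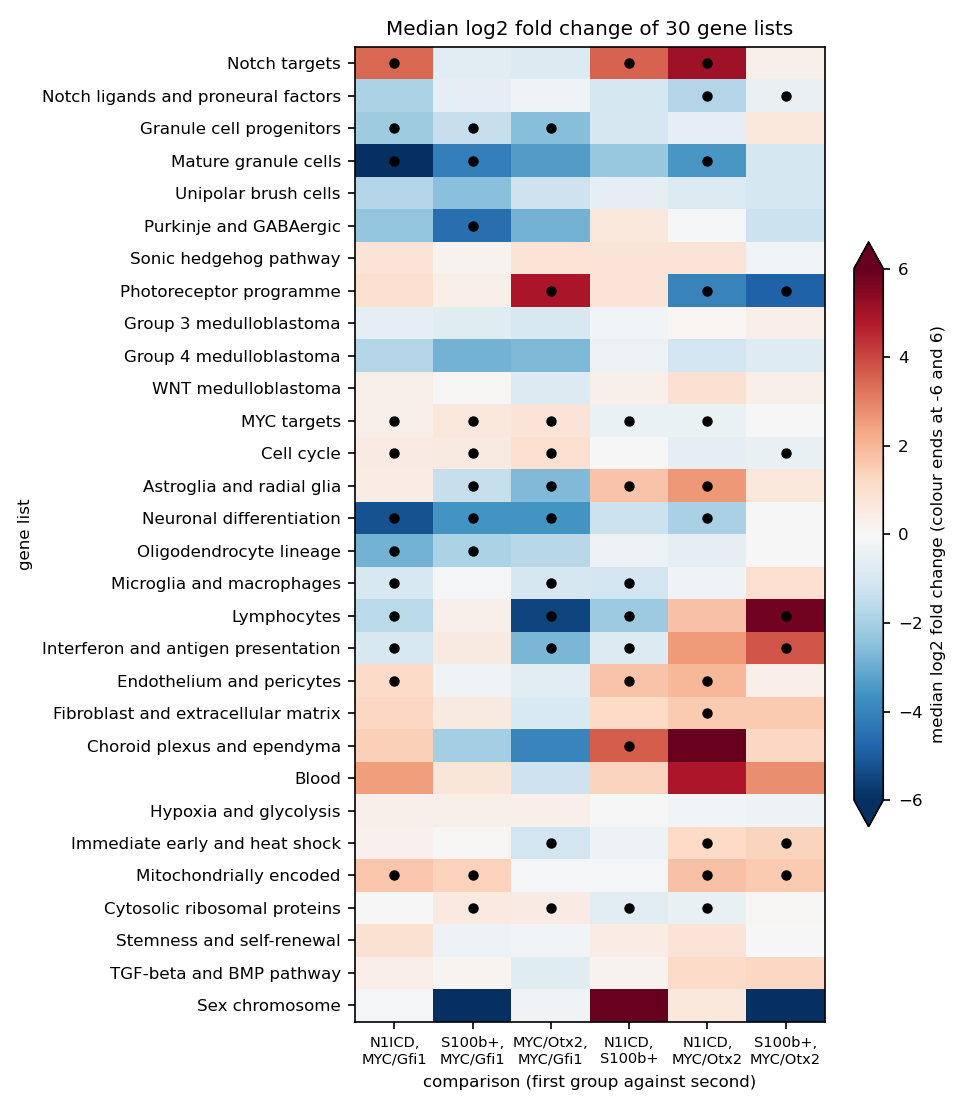
Median log2 fold change of the measured members of each of the 30 lists in the 6 comparisons, blue lower and red higher in the first group, with a dot where camera with its preset correlation passed. The Notch targets reach 3.43, 3.53 and 5.08 in the N1ICD comparisons and the photoreceptor genes 4.89, -4.00 and -4.84 where the MYC/Otx2 tumours take part; 60 of the 61 dots are lost with an estimated correlation.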

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

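All alternatives were chosen before the data were examined, except the replicate block with fry, which was chosen after seeing the data. Results are counts of genes called by edgeR, counts of lists called by camera, and the named genes and lists.

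For the N1ICD against the constitutive MYC/Gfi1 tumours, the 1754 genes became 15 in a fit of these groups alone, 789 with the replicate block, 3369 with DESeq2 and 1014 with limma-voom, and 797 (without N1ICD replicate 2) to 2214 (without MYC/Gfi1 replicate 1). For the S100b-cell against the constitutive MYC/Gfi1 tumours, the 663 became 0 in a fit of these groups alone (3287 at an unadjusted p under 0.05), 102 with the replicate block, 2306 with DESeq2 and 1392 with limma-voom, and 12 (without S100b-cell replicate 1) to 1995 (without MYC/Gfi1 replicate 1). For the N1ICD against the S100b-cell tumours, the 185 became 83 in a fit of these groups alone, 59 with the replicate block and 1360 with DESeq2, and 9 (without S100b-cell replicate 3) to 283 (without MYC/Gfi1 replicate 2). For the MYC/Otx2 against the MYC/Gfi1 tumours, the 832 became 365 in a fit of these groups alone, 209 with the replicate block, 2695 with DESeq2 and 1377 with limma-voom, and 65 (without MYC/Otx2 replicate 3) to 2170 (without MYC/Gfi1 replicate 1). For the N1ICD against the MYC/Otx2 tumours, the 3315 ran from 1654 (without MYC/Otx2 replicate 1) to 4067 (without MYC/Gfi1 replicate 2). For the S100b-cell against the MYC/Otx2 tumours, the 2727 became 4622 in a fit of these groups alone and 4327 with DESeq2, and ran from 1192 (without MYC/Otx2 replicate 3) to 3482 (without MYC/Gfi1 replicate 2). The other settings that keep every library left each count within 1.5 times. Where a group was left with 1 library, that library was assumed to vary like the other groups. Counts rose as well as fell in fits with fewer libraries, and the cause was not tested.

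Camera with its preset correlation called 12, 10, 9, 11, 12 and 7 lists in the same order of comparisons. With an estimated correlation it called 0 in each of the first 5 and 1 in the last, while fry called 9, 1, 2, 2, 9 and 7. The replicate block with fry gave 4, 1, 2 and 1 in the first 4 comparisons, and the stricter filter gave 4 in the last. Without a library the counts ran over 9 to 14, 5 to 12, 7 to 10, 8 to 14, 7 to 15 and 5 to 8. Of the called lists, 5, 3, 4, 8, 5 and 5 passed without each library in turn, and 5, 1, 2, 2, 5 and 4 of these also passed with fry. Over the 61 list calls and all alternatives, 933 of 1147 values stayed past the threshold, 213 did not and 1 turned. The last was the astroglial list of the N1ICD against the S100b-cell tumours, whose camera adjusted p, signed by direction, was -0.875 without N1ICD replicate 1 and 0.419 without S100b-cell replicate 1, against 0.0449 with all.

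The 163 called results for genes taken under the naming rule kept their direction in each of 3377 values under the alternatives and their call in 2621. In settings that keep every library, 1227 of 1430 kept the call. For the 32 named results not called, 586 of 635 values stayed so in the same direction, 27 passed under an alternative and 22 turned. Of the 38 named genes called between the N1ICD and the constitutive MYC/Gfi1 tumours, 36 were lost in a fit of these groups alone and 19 without MYC/Gfi1 replicate 2. Of the 31 called between the S100b-cell and the MYC/Gfi1 tumours, 31 were lost in the fit of these groups alone and 25 without S100b-cell replicate 1. Of the 23 called between the N1ICD and the S100b-cell tumours, 20 were lost without S100b-cell replicate 3. Of the 35 called between the MYC/Otx2 and the MYC/Gfi1 tumours, 30 were lost without MYC/Otx2 replicate 3.

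Directions that turned were those of genes not called, given here in log2 with the lowest and highest value without a library. Gfi1 in the N1ICD against the MYC/Gfi1 tumours, at 0.028, became -0.044 with no filter, -0.67 with the replicate block and -0.34 with limma-voom, and ran from -0.32 to 0.53 (without N1ICD replicates 3 and 2). There Otx2, at 1.52, ran from -2.07 to 3.40 (without N1ICD replicate 1 and MYC/Gfi1 replicate 1). In the S100b-cell against the MYC/Gfi1 tumours, Gfi1 ran from -0.17 to 1.42 (lowest without S100b-cell replicate 1), Notch1 from -0.14 to 4.0 (lowest without S100b-cell replicate 1), Otx2 from -6.64 to 1.09 (highest without MYC/Gfi1 replicate 1) and S100b from -4.33 to 0.28 (highest without MYC/Gfi1 replicate 2). In the N1ICD against the S100b-cell tumours, S100b became 0.61 with limma-voom and ran from -1.17 to 0.47 (highest without S100b-cell replicate 3), and Gfi1 ran from -1.39 to 0.20 (highest without S100b-cell replicate 1). Otx2 ran from -1.24 to 8.17 and Ttr from -1.81 to 8.83 (lowest without N1ICD replicate 1). In the MYC/Otx2 against the MYC/Gfi1 tumours, Notch1 ran from -4.03 to 0 (highest without MYC/Gfi1 replicate 1) and S100b from -4.19 to 0.46 (highest without MYC/Gfi1 replicate 2). Against the MYC/Otx2 tumours, S100b ran from -1.34 to 0.33 in the N1ICD and from -1.28 to 0.95 in the S100b-cell tumours (highest without MYC/Otx2 replicate 2). Notch1 (S100b-cell against MYC/Gfi1 tumours) also turned without MYC/Gfi1 replicate 2, at -0.00805, and S100b (S100b-cell against MYC/Otx2 tumours) without S100b-cell replicate 1, at 0.33. Gfi1 (N1ICD against MYC/Gfi1 tumours) also turned without MYC/Gfi1 replicate 2, at -0.0983, and without N1ICD replicate 1, at -0.28. The cause was not tested.

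Replicate numbers gave no pairing to rest on. Of 15 pairs of same-numbered libraries, 3 correlated above 0.1 after group means were removed, with r from -0.17 to 0.19 over the 15. These 3 pairs all joined replicate 2 libraries, those of the MYC/Gfi1, MYC/Otx2 and S100b-cell groups. The same replicate 2 libraries were the 3 of 11 that correlated best with one of their own number. The N1ICD libraries were the shallowest. Thinning each library to one depth left each count of genes within 1.5 times.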

Other observations

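All tests in this part were chosen after the results they test were seen. Leaving out a library and thinning were planned as alternatives, and only their use as tests of an explanation was chosen afterwards. Each hypothesis here was found in the same data it was tested on.

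The first pattern is the rise of Notch targets in the N1ICD tumours over the S100b-cell tumours. The added N1ICD would give it, but the groups also differ in the cells that express the oncogenes and in library set. The design cannot tell these apart. RNA from mural cells of blood vessels, which also express Notch3 and Heyl, is an alternative, and so is RNA from astroglia, which express Hes5 and Fabp7. In N1ICD replicate 1 the Notch targets lay 1.92 ± 0.93 log2 further above the S100b-cell mean than 8 mural genes, with Acta2 at 24.9 CPM. The SE in this paragraph is taken over genes within 1 library and treats them as independent. Genes of a list may move together, so it can be too small. The 1.92 therefore argues only weakly against mural cells as the whole source in that library. The difference was -3.49 ± 1.46 in replicate 2, with Acta2 at 2584 CPM, and -0.17 ± 0.91 in replicate 3. This leaves mural cells open as a source of the list's rise in those libraries. Hey2, Heyl and Nrarp varied far less than Acta2 over the N1ICD libraries, but they were not tested apart from the list. The Notch target median itself was 3.03, 0.76 and 3.45 log2 above the S100b-cell mean in replicates 1, 2 and 3. In replicate 2 the SD over its genes was 3.00 and the mural median 4.25, so the list as a whole rose little there. Against 33 astroglial genes the difference was 0.44 ± 0.90 in replicate 1, with Slc1a3 at 1402 CPM, which leaves astroglia open there. It was 2.33 ± 1.06 and 3.72 ± 0.73 in replicates 2 and 3, with Slc1a3 at 4.18 and 26.0 CPM. The astroglial medians there were -1.57 and -0.27 against the S100b-cell mean. This argues against astroglia as the whole source in replicate 3, and only weakly in replicate 2 given its SE.

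The second pattern is the low level of neuronal genes against the constitutive MYC/Gfi1 tumours, in which replicate 2 held Cbln3 at 1159 CPM. Mature cerebellar tissue in that library may be part of the cause. Without it, the neuronal list still passed with camera in the N1ICD (adjusted p = 5.25e-05), S100b-cell (1.66e-05) and MYC/Otx2 tumours (0.0290). The list's median went from -5.24, -3.61 and -3.60 to -2.74, -1.21 and -1.33, so it shrank but stayed negative. The MYC/Gfi1 group then held only its other library, assumed to vary like the other groups. The estimated correlation was not run in that setting. These p-values therefore cannot decide whether replicate 2 is the whole cause, which stays open. With all libraries the list's camera adjusted p was 3.07e-10, 3.00e-12 and 2.04e-06, and 0.570, 0.797 and 0.668 with an estimated correlation. For the mature granule cell list in the S100b-cell tumours, the adjusted p was 0.314 without the library and the median went from -4.12 to -0.67, so for these genes the library and the model cannot be told apart.

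The third pattern is a wide spread of log2 fold changes over the 46 ribosomal protein genes between the S100b-cell and the constitutive MYC/Gfi1 tumours, with an SD of 0.889. Most of it came from Rpl26, at 369 to 569 CPM in the S100b-cell libraries and 9.09 to 21.6 CPM in the others, and only 2 of the 46 genes, Rpl26 and Rps14, lay more than 1 from the median. Between the constitutive groups, whose libraries share a naming style, the SD was 0.251, and without the gene farthest from the median the values were 0.534 and 0.230. A difference between library sets may be a source, for Rpl26 above all, and since the sets follow the groups, the design keeps this open, along with reads shared with pseudogenes and a difference between the models, neither of which was tested. With each library thinned to one depth the SD was 0.881. Thinning keeps the expected ratios between libraries, so this SD could hardly fall, and no conclusion on unequal depth is drawn from it.

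With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. A split that mixes the groups also puts any difference between them into the spread within groups, which lowers its count of genes. The low gene counts of the other splits are therefore no support for the real split. For the N1ICD against the S100b-cell tumours, 1 of 10 splits gave as many genes as the real 185, the highest other giving 3, and 7 of 10 gave as many lists as the real 9, the highest other giving 13. For the N1ICD against the MYC/Otx2 tumours, 1 of 10 gave as many as the real 3315 genes, the highest other giving 0, and 4 of 10 as many as the real 12 lists, the highest other giving 16. For the S100b-cell against the MYC/Otx2 tumours, 1 of 10 gave as many as the real 2727 genes, the highest other giving 0, and 10 of 10 as many as the real 7 lists, the highest other giving 10. In each of these comparisons a split that mixed the groups gave more lists than the real split.

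Ddx3y, a gene of the Y chromosome, was at 87.7, 67.3 and 110 CPM in MYC/Gfi1, MYC/Otx2 and N1ICD replicate 2 and at 0.141 CPM or less in the other 8 libraries. Xist, which is expressed from the inactive X chromosome, was at 0.581, 5.73 and 0.349 CPM in those 3 libraries and at 131 to 789 CPM in the others. The labels used here give no sex for the animals. H2-Aa, a class II gene, was at 31.8 CPM in MYC/Otx2 replicate 1 and 3.61 and 1.39 CPM in replicates 2 and 3, and at 30.7 CPM in N1ICD replicate 2 and 3.00 and 1.62 CPM in replicates 1 and 3.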
